A study of Homo sapiens with 18 samples.

How the data were processed

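The series holds bulk RNA sequencing of xenograft tumours, that is, tumours collected from mice that carried human neuroblastoma cell lines. The lines were SK-N-AS (SKNAS in the labels), LAN-1 and KELLY. Each line had a control arm and an arm named Hmx1, with 3 libraries per arm, 18 libraries and 6 groups in all. Groups were taken from the sample titles. Replicate numbers were given in accession order and pair no libraries. The labels do not say whether Hmx1 was raised or lowered, nor from which species its sequence came. They do not say that libraries of a group came from separate animals, so the p-values of single genes rest on the spread between these libraries, which may be technical. In the main fit that spread was pooled over the 6 groups. Tests of gene lists, of overlaps and of X-linked calls compare genes with genes, and do not measure the spread between animals either.

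Per the labels' protocols, RNA was extracted with a lipid tissue kit, libraries were made with a stranded poly(A) kit and sequenced as read pairs of 125 bp in 2 lanes. Per the submitters' processing notes, bcl2fastq, FastQC and STAR were used, and the builds GRCh38.p12 and GRCh37 are named with no role. The tool that made the gene tables, the gene annotation, the use of strand and whether reads of mouse origin were removed are not given in the sources used here. Values of host and muscle markers can therefore include mouse reads assigned to human genes. The same holds for matrix and mesenchymal genes, whose lists share members with the host fibroblast list. Without a stated use of strand, reads of overlapping genes on opposite strands may not have been told apart, and reads of near-identical copies may have been split between them.

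Each library has its own gene table. TPM, the share of transcripts scaled to a fixed total, is a deposited column per the file headers and sums to 1e+06 in every library. FPKM, the depth- and length-normalized fragment value, is also a deposited column per the file headers and served as an alternative unit. The deposited Coverage column, a coverage signal per gene per the file headers, was used only to look at the relation between the columns. TPM keeps no depth, so the number of reads per library is unknown and no counting interval can be given. The values were not multiples of whole reads, so a count model was not used. Coordinates are those of the files. The last gene on chromosome 1 ended at 249231242, beyond the last gene end of 248937099 in the RefSeq GRCh38 annotation, and the files were therefore read as GRCh37 coordinates.

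The tables list 63677 gene identifiers. Of these, 52181 received a symbol from a separate gene name reference and 52526 a biotype from GENCODE v29, both matched by identifier. Those with a symbol carried 98.7% to 98.9% of the TPM of a library. GENCODE gave biotypes, GC content and the names of list members that matched no symbol, and no coordinates. Between 8 and 12 identifiers per library stood on more than 1 line, and their TPM were summed. No 2 replicate libraries were copies of each other: Pearson's r across genes was 0.961 to 0.989 within groups, and at most 1 gene had the same TPM above 0 in a pair.

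All tests used log2(TPM + 1). Genes with a TPM of at least 1 in at least 3 libraries were tested, 18650 in all. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. limma 3.58.1 in R 4.3.3 was fitted to all 18 libraries with 6 group means and a mean-variance trend in the prior, which left 12 residual and 4.95 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called changed at an adjusted p under 0.05. There were 10 comparisons: Hmx1 against control within each line, the mean of those 3 effects, the 3 differences between them, and the 3 differences between control arms. HMX1, HMX2, HMX3 and MYCN were also compared by exact two-sided permutation of 3 against 3 libraries, whose smallest p is 0.1, and, for HMX1, HMX2 and MYCN, by relabelling arms within the lines. Overlaps of calls between lines were compared with n1 × n2 / N and tested with a one-sided Fisher's exact test, 6 tests for calls in the same direction and 6 for calls in opposite directions, each 6 adjusted together. Principal components were computed per line from the log2(TPM + 1) values of the genes tested.

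The 29 gene lists were noradrenergic identity, cholinergic, mesenchymal identity, chromaffin, Schwann cell precursor, bridge and committed progenitor, neuronal differentiation, neurotrophin and GDNF receptors, cell cycle, MYC and MYCN targets, p53 and apoptosis, hypoxia, unfolded protein response, interferon response, antigen presentation, TGF-beta and extracellular matrix, retinoic acid response, cholesterol synthesis, host endothelium, host macrophage and leukocyte, host fibroblast, skeletal muscle, skin epithelium, adipocyte, erythroid, mitochondrial transcripts, immediate early and dissociation stress, replication-dependent histones, and ribosomal proteins. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists with enough members. The erythroid list had 1 member above the TPM minimum and could not be tested. With the correlation estimated per list, none of the 23 list calls in the within-line and mean comparisons remained, and the p from that fit is given beside each call.

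Genes are named by a fixed rule. In each within-line comparison and in the mean, these are the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those with an adjusted p under 0.05, a mean of at least 5 TPM in the higher arm and arms that do not overlap (for the mean: the same sign in the 3 lines). In differences between effects and between controls, 3 at each end are named, without the overlap criterion for the former. HMX1, HMX2, HMX3 and MYCN are always named, and up to 4 members per list with the smallest adjusted p can be named. Mitochondrial genes (outside their list), Y-linked genes and XIST were left out of the rule. Genes named outside it are said to be so. Only part of the list members that the rule allows are printed, a choice not fixed beforehand, and the others are not reported here.

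The fit was tested on simulated data with 200 of the 18650 genes changed. Each gene had the same spread in every line, and genes varied independently. In the data, the variance of log2 changes expected from library spread was 0.123 in KELLY, 0.0493 in SKNAS and 0.0559 in LAN-1. The simulation therefore does not give the recovery or the false calls at the spread of a single line. At a log2 change of 1 it recovered 57.5% of them in SKNAS with 10 false calls, 51.0% in LAN-1 with 11, and 53.0% in KELLY with 4. At a log2 change of 2 it recovered 96.0%, 95.5% and 95.5%, with 13, 8 and 8 false calls.

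The tests, the lists, the naming rule and the alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 4, no filter on low values, a minimum of 5 TPM, FPKM in place of TPM, median-ratio scaling, quantile normalization, TPM rescaled without mitochondrial genes and the 50 most abundant genes, a fit of the compared groups alone, library weights, no trend, a robust prior, leaving out each library, ranks or an estimated correlation in the list tests, and thresholds of an adjusted p under 0.01 or an added log2 change of at least 1. Chosen after seeing the data were means over pairs of lines, the mitochondrial share as a covariate, genes outside shifted chromosome stretches, and the analysis of those stretches, of X-linked calls with and without cancer-testis families (MAGEA, MAGEB, MAGEC, CSAG, CTAG, GAGE, XAGE, PAGE, SSX, SPANX and CT genes by symbol) and of fold variance. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.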

Results

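Polyadenylated RNA was measured in 18 xenograft tumour libraries of the human neuroblastoma lines SKNAS, LAN-1 and KELLY, with 3 control and 3 Hmx1 libraries per line. The number of reads behind each library is unknown because TPM keeps no depth. Between 21590 and 24901 genes lay above 0 TPM per library, and between 14420 and 16441 reached 1 TPM. Mitochondrial transcripts took from 4.47% to 33.8% of the TPM of a library, and the 50 most abundant genes took from 22.4% to 50.6%. The mitochondrial share was 17.7% ± 3.07 in SKNAS control and 16.8% ± 2.64 in SKNAS Hmx1 (SD, n = 3 in every group). It was 6.21% ± 0.431 and 5.40% ± 1.45 in the LAN-1 arms, and 25.5% ± 11.1 and 18.5% ± 2.54 in the KELLY arms. Values below are TPM as mean ± SD over 3 libraries, log2 changes come with their standard error (SE), and adjusted p-values are those of limma.

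HMX1 (ENSG00000215612, GRCh37 chromosome 4, 8847802 to 8873543), the homeobox gene that names the treated arm, was listed at 0 in all 3 SKNAS control libraries and at 0.193 to 1.24 TPM in the SKNAS Hmx1 libraries. The difference did not pass the test over all genes (adjusted p = 0.127), and the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. In LAN-1 it stood at 11.6 ± 0.413 TPM in control and 13.2 ± 2.89 in Hmx1 libraries (log2 change 0.15, adjusted p = 1). In KELLY it stood at 5.70 ± 1.91 and 5.50 ± 0.861 TPM (log2 change -0.01, adjusted p = 1). The exact permutation p was 0.7 in LAN-1 and 0.9 in KELLY, and relabelling the arms within the 3 lines gave an exact stratified p of 0.09 over 8000 relabellings. The difference thus passed over all genes in none of the lines. The SKNAS call depends on the scale, since HMX1 passed with a pseudocount of 0.1 (log2 change 2.55, adjusted p = 0.000562). It also passed with library weights (log2 change 0.65, adjusted p = 0.0382), whose estimate did not converge and gave 1 KELLY library a weight of 130.0.

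HMX2, a paralogue of HMX1, rose in SKNAS from 7.41 ± 1.98 to 18 ± 3.14 TPM (log2 change 1.19, SE 0.22, adjusted p = 0.00163). It stood at 7.15 ± 2.53 and 11.8 ± 1.44 TPM in the LAN-1 arms (adjusted p = 0.324), and at 0.0998 and 0.0733 TPM in the KELLY arms. Its exact stratified p over the 3 lines was 0.006. HMX3 did not reach the TPM minimum of the test. It was at 0.775 ± 0.674 and 0.316 ± 0.177 TPM in the SKNAS arms and at 0.626 ± 0.285 in LAN-1 Hmx1 libraries, and was listed at 0 in LAN-1 control and in all 6 KELLY libraries. MYCN, the oncogene that is amplified in LAN-1 and KELLY, stood at 867 ± 30.5 and 787 ± 54.0 TPM in the LAN-1 arms and at 1424 ± 533 and 1472 ± 347 in the KELLY arms. In SKNAS it was near 0, at 0.0469 and 0.0502 TPM. MYCN did not pass in any line (adjusted p = 1 in each; exact stratified p = 0.89).

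**Figure D1:**
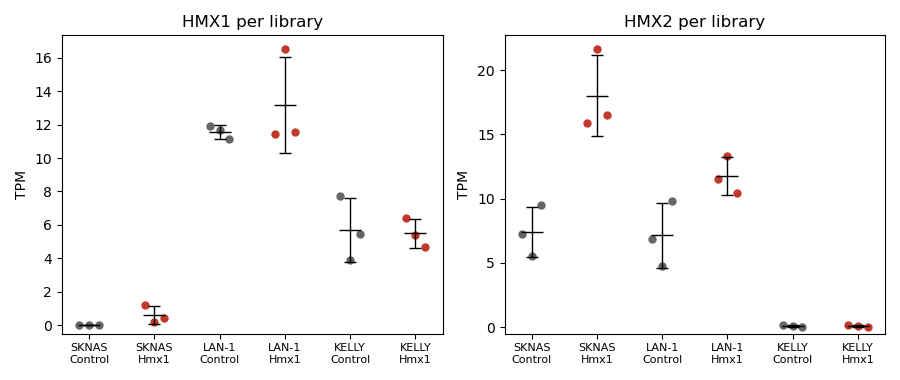
TPM of HMX1 and HMX2 in each library (points) by line and arm, with the mean and SD of each group of 3 libraries (bars). HMX1 is listed at 0 in the 3 SKNAS control libraries and lies at 0.193 to 1.24 TPM in the SKNAS Hmx1 libraries, and HMX2 lies higher in SKNAS Hmx1 (18 ± 3.14 TPM) than in SKNAS control libraries (7.41 ± 1.98).

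In SKNAS, the largest rises among protein-coding genes were those of CCL2, a monocyte chemoattractant, and NPTX2, a neuronal pentraxin. CCL2 (ENSG00000108691, GRCh37 chromosome 17, 32582304 to 32584222) went from 3.62 ± 0.840 to 199.5 ± 46.8 TPM (log2 change 5.43, SE 0.21, adjusted p = 1.6e-11). NPTX2 (ENSG00000106236, chromosome 7, 98246609 to 98259180) went from 7.08 ± 1.46 to 274 ± 58.8 TPM (log2 change 5.08, SE 0.18, adjusted p = 7.92e-12). Some cancer-testis genes on the X chromosome also rose. Of 26 tested members of such families, 11 were called as rises and 2 as falls, a tally made after the rises were seen. MAGEA12 went from 0.718 to 47.0 ± 6.56 TPM (log2 change 4.81), CSAG1 from 0.453 to 28.1 (4.33), CTAG1B from 0.359 to 23 (4.19), MAGEA3 from 2.11 to 43.1 (3.82) and MAGEA6 from 3.55 to 48.2 (3.29). MAGEA2B was listed at 0 in control and at 22.9 ± 5.27 TPM in Hmx1 libraries. Not all such genes rose: MAGEA1 fell from 192 to 24.6 TPM (-2.94) and MAGEC1 from 44.2 to 7.16 (-2.48), both chosen after their values were seen. Members of these families have near-identical copies, so their single values are uncertain. The zinc finger gene ZNF22 rose from 0.254 to 13.9 ± 3.74 TPM (3.55). The read-through gene BIVM-ERCC5, which shares its sequence with its constituent genes, went from 6.34 ± 11 to 32.0 ± 3.11 TPM, with an adjusted p of 0.0397 that 10 of 18 alternatives ended.

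The largest SKNAS falls among protein-coding genes were those of a pair of neighbouring secreted-protein genes on chromosome 4. FDCSP (ENSG00000181617, 71091788 to 71100969) went from 46.0 ± 14.1 to 0.788 ± 0.684 TPM (log2 change -4.77, SE 0.24, adjusted p = 4.02e-10). ODAM (ENSG00000109205, 71062213 to 71070293) went from 47.9 ± 1.15 to 1.42 ± 0.359 TPM (log2 change -4.35, SE 0.13, adjusted p = 6.59e-13). A pair of neighbouring C-type lectin genes on chromosome 12 fell as well, CD69 from 23.2 to 1.15 TPM (-3.50) and CLEC2B from 54.1 to 4.46 (-3.33). EPHA3, an ephrin receptor, fell from 33.4 ± 3.43 to 2.66 TPM (-3.25), BMP5, a bone morphogenetic protein, from 23.9 to 1.84 (-3.13), TLL1, a tolloid-like protease, from 17.0 to 0.923 (-3.22), and MYOC, myocilin, from 140.0 ± 35.5 to 16 (-3.06). LRRC61 went from 19.6 to 1.11 TPM (-3.31) and GNGT1 from 27.2 to 1.90 (-3.29). Except for BIVM-ERCC5, the 20 SKNAS genes of the naming rule passed under all 18 alternatives.

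Over all genes in SKNAS, 925 rose and 709 fell of 18650 tested, and 788 of these 1634 changed by at least 1 on the log2 scale. The 3 control and 3 Hmx1 libraries did not overlap for 5756 genes, 30.9% of those tested, where chance gives 10%. Nothing in the labels ties a library to an animal, and genes are not independent replicates.

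**Figure D2:**
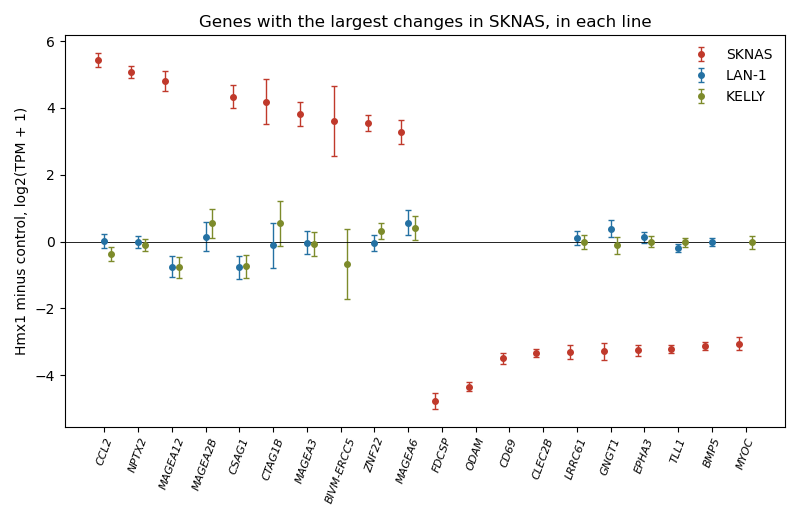
Change of the named SKNAS genes with Hmx1 on the log2(TPM + 1) scale in each line, as the fitted difference from control with its SE (bars; 3 against 3 libraries per line), with no point where all control libraries of the line are listed at 0. CCL2 stands at 5.43 in SKNAS, and FDCSP at -4.77.

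Among the lists of neural identity in SKNAS, the mesenchymal identity genes were lower as a list (median log2 change -0.32, adjusted p = 0.00131; adjusted p = 0.825 with an estimated correlation). Of 31 members, 2 rose, 7 fell and 22 did not pass, and adjusted over the list alone 2 rose and 12 fell. The receptor NOTCH2 (-1.23), the transcription factor SNAI2 (-0.997) and RUNX1 (-0.78) fell, and the homeobox gene MEOX2 rose (1.11). The mesenchymal list shares PDGFRA and PDGFRB with the host fibroblast list, so its values can include mouse reads assigned to human genes. No other neural list passed. Of 25 noradrenergic identity genes, 2 rose, 3 fell and 20 did not pass (adjusted over the list alone, 3 and 5; adjusted p = 0.166). TFAP2B fell by 2.27 on the log2 scale and TH, which encodes tyrosine hydroxylase, fell by 1.81, whereas CHGA, chromogranin A, rose by 0.89. Of 15 cholinergic genes, 1 rose, 3 fell and 11 did not pass (adjusted over the list alone, 1 and 4; adjusted p = 0.615). LHX8 rose (2.70), and SLC5A7 (-1.51), CHAT (-0.81) and SLC18A3 (-0.77) fell. Chromaffin genes had 2 rises, 0 falls and 13 not passed of 15 (adjusted over the list alone, 2 and 1; adjusted p = 0.743), with GAL at 1.25.

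Of 12 Schwann cell precursor genes in SKNAS, 2 rose, 1 fell and 9 did not pass (adjusted over the list alone, 3 and 1; adjusted p = 0.582), among them MPZL2 (1.10), S100B (0.83) and SOX9 (-0.73). Of 11 bridge and committed progenitor genes, 1 rose, 2 fell and 8 did not pass (adjusted over the list alone, 1 and 2; adjusted p = 0.51), with HTR3A at 2.23 and NEUROG2 at -0.85. Neuronal differentiation genes had 4 rises, 3 falls and 21 not passed of 28 (adjusted over the list alone, 7 and 4; adjusted p = 0.51). The neurofilament gene NEFM (1.51) and RTN1 (1.09) rose, and the tubulin gene TUBB2B (-1.47) and UCHL1 (-0.84) fell. Of 13 neurotrophin and GDNF receptor genes, 2 rose, 1 fell and 10 did not pass (adjusted over the list alone, 2 and 3; adjusted p = 0.615), with ALK at 1.13, GDNF at 0.90 and GFRA2 at -0.93.

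Among the lists on growth and signalling in SKNAS, 4 passed. Each had an adjusted p of 0.825 with an estimated correlation. Cell cycle genes were lower (median -0.25, adjusted p = 0.000168), with 0 rises, 4 falls and 37 not passed of 41, and the same counts of 0 and 4 adjusted over the list alone. CDK1 fell by 0.92, RRM2 by 0.87, AURKB by 0.66 and CDC20 by 0.56 on the log2 scale. Interferon response genes were lower (median -0.37, adjusted p = 0.000168), with 1 rise, 8 falls and 17 not passed of 26 (adjusted over the list alone, 1 and 10). ISG20 (-1.44), IFI44L (-0.96) and TAP1 (-0.73) fell, and BST2 rose (1.24). Unfolded protein response genes were lower (median -0.34, adjusted p = 0.00361), with 0 rises, 1 fall and 18 not passed of 19 (adjusted over the list alone, 0 and 1), and MANF fell (-0.71). Cholesterol synthesis genes were lower (median -0.37, adjusted p = 0.00361), with 0 rises, 1 fall and 22 not passed of 23 (adjusted over the list alone, 0 and 0). MSMO1 fell (-0.88), and the list did not pass without SKNAS control replicate 1.

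The other signalling lists did not pass in SKNAS although single members did. MYC and MYCN targets had 1 rise, 1 fall and 27 not passed of 29 (adjusted over the list alone, 1 and 1; adjusted p = 0.743), with PHGDH at -1.05 and SRM at 0.49. Of 20 p53 and apoptosis genes, 3 rose, 0 fell and 17 did not pass (adjusted over the list alone, 3 and 2; adjusted p = 0.615), with BBC3 at 1.02, FAS at 0.82 and FDXR at 0.64. Of 30 hypoxia genes, 4 rose, 2 fell and 24 did not pass (adjusted over the list alone, 4 and 3; adjusted p = 0.517), with STC2 at 1.03, ENO1 at 0.80, CA9 at -1.61 and P4HA2 at -0.99. Antigen presentation had 4 rises, 4 falls and 8 not passed of 16 (adjusted over the list alone, 5 and 6; adjusted p = 0.655). The class II genes CD74 (2.25) and HLA-DPA1 (1.18) rose, and the immunoproteasome genes PSMB9 (-1.70) and PSMB8 (-1.16) fell. Of 30 TGF-beta and extracellular matrix genes, 5 rose, 5 fell and 20 did not pass (adjusted over the list alone, 5 and 8; adjusted p = 0.259), with TIMP3 at 2.59, SMAD7 at 1.98, COL12A1 at -2.32 and COL5A2 at -1.29. Of 14 retinoic acid response genes, 3 rose, 3 fell and 8 did not pass (adjusted over the list alone, 3 and 4; adjusted p = 0.51), with ALDH1A2 at 2.18, DHRS3 at 1.02, NRIP1 at -1.91 and CRABP1 at -1.82.

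Markers of other cell types did not pass as lists in SKNAS. Whether mouse reads were removed is not given in the sources used here, so the values of host, muscle, skin and fat markers can include mouse reads assigned to human genes. Host endothelium had 1 rise, 1 fall and 5 not passed of 7 (TEK 1.03, ENG -1.19; adjusted p = 0.729), and host macrophage and leukocyte had 1, 1 and 1 of 3 (PTPRC 1.31, CD14 -0.62; adjusted p = 0.615), with the same counts adjusted over the list alone. Host fibroblast had 0 rises, 3 falls and 11 not passed of 14 (adjusted over the list alone, 2 and 3; PDGFRA -0.86, LUM -0.81, DPT -0.49; adjusted p = 0.322). Skeletal muscle had 0, 1 and 6 of 7 (adjusted over the list alone, 0 and 1; TNNI2 -1.16; adjusted p = 0.462), skin epithelium 1, 0 and 2 of 3 (adjusted over the list alone, 1 and 1; KRT17 1.61; adjusted p = 0.743), and adipocyte 0, 0 and 3 of 3 (adjusted over the list alone, 0 and 0; adjusted p = 0.729). For the erythroid list, no test was possible with 1 member. Among the lists on RNA quality, ribosomal proteins were higher (median 0.34, adjusted p = 6.12e-06; adjusted p = 0.825 with an estimated correlation), with 3 rises, 0 falls and 29 not passed of 32, and 3 and 0 adjusted over the list alone. RPL4 (1.12), RPS4X (0.82) and RPL3 (0.69) rose, and such genes have many near-identical pseudogenes. Mitochondrial transcripts had 0 rises, 1 fall and 12 not passed of 13 (adjusted over the list alone, 0 and 1; MT-ATP6 -1.97; adjusted p = 0.729). Immediate early and dissociation stress had 1, 1 and 13 of 15 (adjusted over the list alone, 1 and 2; MYC -1.98, IER3 0.96; adjusted p = 0.288), and replication-dependent histones 0, 1 and 10 of 11 (adjusted over the list alone, 0 and 1; H1-2 -0.89; adjusted p = 0.24).

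In LAN-1, the largest rise among protein-coding genes was that of CPNE4, a calcium-dependent phospholipid-binding copine (ENSG00000196353, chromosome 3, 131252399 to 132004254). It went from 3.92 ± 0.329 to 36.5 ± 3.15 TPM (log2 change 2.93, SE 0.23, adjusted p = 1.71e-06). PODN rose from 0.904 to 6.42 ± 0.510 TPM (1.96, adjusted p = 2.38e-06), CNOT4, a subunit of the CCR4-NOT complex, from 13.7 ± 0.540 to 47.5 ± 3.62 (1.72, adjusted p = 0.000125), and ASS1, argininosuccinate synthase, from 327 ± 17.8 to 755 ± 12.6 (1.20, adjusted p = 0.00134). The largest fall among them was that of ACTL8, an actin-like gene (ENSG00000117148, chromosome 1, 18081808 to 18153558), from 25.1 ± 2.44 to 1.67 ± 0.162 TPM (log2 change -3.29, SE 0.19, adjusted p = 1.78e-08). CYB561, a cytochrome of catecholamine vesicles, fell from 20.9 ± 0.896 to 6.71 TPM (-1.51, adjusted p = 0.00118). These 6 genes passed under all 18 alternatives.

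The other named LAN-1 genes lost their call under at least 1 alternative. ADD2 (2.08 to 8.94 TPM), FRRS1L (1.25 to 5.84), TMOD1 (18 to 53.3) and PRSS3 (3.27 to 9.77) rose, and the neuronal transcription factor NEUROD1 (27.2 ± 11.6 to 6.97), SNCG, gamma-synuclein (24.4 to 8.38), and CD163L1 (7.51 to 1.49) fell. These 7 did not pass when LAN-1 was fitted alone. MXD1 (3.33 to 10.3 TPM) and AOPEP (29.1 to 83.4 ± 33.3) rose, and ENPP2 (33.8 to 12), HPCA (9.68 to 2.73), MRC2 (5.32 to 1.37), SCG5 (9.04 to 3.05) and PYGM (15.7 to 6.04) fell. AOPEP and MXD1 lost the call in 4 alternatives each, and SCG5, with the most, in 8. Across all genes in LAN-1, 32 rose and 52 fell, 57 of these 84 by at least 1 on the log2 scale, and 2950 genes (15.8%, against 10% by chance) did not overlap between arms. The share of rises was 38.1%, 50% with median-ratio scaling and 58.6% with quantile normalization. A fit of LAN-1 alone called 27 genes, the fit without LAN-1 control replicate 1, control replicate 2 or Hmx1 replicate 3 called 54 each, and that without Hmx1 replicate 2 called 53. More genes than the 84 were called with median-ratio scaling, quantile normalization, FPKM or no filter, with the counts given below. LAN-1 Hmx1 replicate 1 stood apart from its arm. On the first principal component of the line (37% of the variance) it lay at -18, among the controls (-21.4 to -7.9), and the other Hmx1 libraries lay at 38.3 and 28.1. Its mitochondrial share was 7.07%, against 4.66% and 4.47%, and without it 99 genes were called.

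Cholesterol synthesis genes were higher as a list in LAN-1 (median 0.29, adjusted p = 1.19e-07). None of the 23 members passed over all genes and 2 rose adjusted over the list alone, with IDI1 at 0.77 (adjusted p = 0.0757 over all genes) and STARD4 at 0.71. Hypoxia genes were lower (median -0.23, adjusted p = 0.00766), with 0 of 30 members passing either way, and the list did not pass without LAN-1 control replicate 1, Hmx1 replicate 1 or Hmx1 replicate 2. Neuronal differentiation genes were higher by a small margin (median 0.03, adjusted p = 0.0367), with 0 of 28 members passing either way. That call was lost in 6 of 25 alternatives, among them leaving out control replicate 1 or 2 or Hmx1 replicate 1 or 3. All 3 lists had an adjusted p of 0.886 with an estimated correlation. Outside these lists, CYB561 was the only noradrenergic member that passed, BST2 fell (-1.03, adjusted p = 0.0258) and TAP2 rose (0.93, adjusted p = 0.0339).

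In KELLY, 9 genes rose and 8 fell, 13 of these 17 by at least 1 on the log2 scale. TCEAL7, a transcription elongation factor A-like gene (ENSG00000182916, X chromosome, 102585124 to 102587254), rose from 7.13 ± 2.09 to 28.1 ± 6.25 TPM (log2 change 1.84, SE 0.21, adjusted p = 0.00162). FABP6, a bile acid-binding protein gene, rose from 22.8 ± 0.733 to 63.1 ± 12.5 TPM (1.41, adjusted p = 0.00863), SPINK5 from 3.79 to 7.49 (0.82, adjusted p = 0.0331), and CTAG2, which has near-identical copies, from 63.9 to 144 ± 38.8 (1.17, adjusted p = 0.0444). DAG1, dystroglycan (ENSG00000173402, chromosome 3, 49506146 to 49573048), fell from 21 ± 10.1 to 1.80 ± 0.558 TPM (log2 change -2.87, SE 0.43, adjusted p = 0.00861). UBB, a polyubiquitin gene with related copies, fell from 15.2 ± 10.4 to 2.65 TPM (-1.99, adjusted p = 0.00804), ENSG00000241962, a gene model without a symbol, from 12.5 to 3.31 (-1.66, adjusted p = 0.00861), and the zinc finger gene ZFP57 from 16.9 to 8.49 (-0.96, adjusted p = 0.0444). With KELLY fitted alone, limma called 0 genes. In the fit of all lines, 1277 had an unadjusted p under 0.05, and 1244 (6.70%, against 10% by chance) did not overlap between arms. Without KELLY control replicate 1, control replicate 2 or Hmx1 replicate 1, the counts of called genes were 29, 49 and 27. CTAG2 lost its call in 11 of 18 alternatives, ZFP57 in 9, SPINK5 in 7, and FABP6 in 2 (KELLY fitted alone and without Hmx1 replicate 3). The share of rises, 52.9%, was 33.3% with TPM rescaled without mitochondrial and abundant genes.

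No list member passed over all genes in KELLY, where the mitochondrial share of the control libraries was 33.8%, 12.9% and 29.6%. Hypoxia genes were higher (median 0.27, adjusted p = 0.000215; 1 of 30 rose adjusted over the list alone; adjusted p = 0.596 with an estimated correlation), with SLC2A1 at 0.72 and HK2 at 0.69. Unfolded protein response genes were higher (median 0.27, adjusted p = 0.002; adjusted p = 0.618 with an estimated correlation), but not without control replicate 1 or 2. Ribosomal proteins were higher (median 0.22, adjusted p = 0.00033; adjusted p = 0.78 with an estimated correlation). That list lost its call with quantile normalization and without control replicate 2 or 3, and turned direction without Hmx1 replicate 3 (adjusted p = 0.915). Mitochondrial transcripts were lower (median -0.38, adjusted p = 0.000215; adjusted p = 0.708 with an estimated correlation), lost the call with quantile normalization and without control replicate 3, and turned direction without control replicate 1 (adjusted p = 0.976).

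Of the 4 other KELLY lists that passed, replication-dependent histones were higher (median 0.35, adjusted p = 0.0145; 2 of 11 rose adjusted over the list alone; adjusted p = 0.596 with an estimated correlation). Skeletal muscle (median -0.63, adjusted p = 0.0143; adjusted p = 0.596 with an estimated correlation), cholinergic genes (median -0.20, adjusted p = 0.0143; adjusted p = 0.596 with an estimated correlation) and TGF-beta and extracellular matrix (median -0.12, adjusted p = 0.0137; adjusted p = 0.762 with an estimated correlation) were lower. The muscle and matrix values can include mouse reads assigned to human genes. Of 30 matrix genes, 1 fell adjusted over the list alone, and of the unfolded protein response, ribosomal, mitochondrial, muscle and cholinergic genes, 0 passed adjusted over the list alone. The histone list did not pass without control replicate 2, Hmx1 replicate 2 or Hmx1 replicate 3, nor by ranks, and the muscle list not without control replicate 1, control replicate 2 or Hmx1 replicate 2. The cholinergic and matrix lists did not pass without control replicate 1, control replicate 3 or Hmx1 replicate 3, and the cholinergic list also not with a minimum of 5 TPM.

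As a mean over the 3 lines, 368 genes rose and 292 fell with Hmx1, and 253 of these 660 had the same sign in each line. PDLIM1, a PDZ and LIM domain gene (ENSG00000107438, chromosome 10, 96997329 to 97050781), rose (mean log2 change 1.504, SE 0.12, adjusted p = 6.06e-07). It went from 0.109 to 7.51 TPM in SKNAS, from 1.29 to 4.45 in LAN-1 and from 38.1 to 48.5 in KELLY. YBX3, a cold shock domain gene (ENSG00000060138, chromosome 12, 10851683 to 10875911), fell (-1.21, SE 0.11, adjusted p = 2.54e-06), from 58.7 to 13.9, from 3.25 to 0.493 and from 0.880 to 0.696 TPM. FLRT2 (-1.04, adjusted p = 0.00303) went from 4.66 to 1.27, from 8.17 to 3.81 and from 9.88 to 5.78 TPM, and ELMO1 (-1.02, adjusted p = 0.000554) from 6.52 to 1.03, from 9.38 to 5.15 and from 16 to 11.3.

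The other named rises in the mean were MAGEA2B (1.75), MAGEA6 (1.42), FGL1 (1.22), ARMCX2 (1.15), DNER (1.12), VAT1L (1.07), LCP1 (0.95), ZNF528 (0.93) and NUDT7 (0.93). The other falls were TLL1 (-1.15), CSTF2T (-1.04), IGDCC3 (-0.98), GPRASP3 (-0.98), NEUROD4 (-0.93), IRS2 (-0.92) and SNCG (-0.90). GPRASP3 lost its call in 4 of 29 alternatives (a pseudocount of 0.1, no filter, and without SKNAS control replicate 1 or 3), and LCP1 in 1 (a pseudocount of 4). Several of these rested on SKNAS: FGL1 went from 26.6 to 203 TPM there and IRS2, an insulin receptor substrate, from 65.7 to 10.4. In all, 581 of the 660 genes were also called in SKNAS, and a mean over LAN-1 and KELLY alone, an alternative chosen after seeing the data, called 28.

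Ribosomal proteins were higher in the mean (median 0.23, adjusted p = 9.06e-10), with 2 of 32 rising over all genes and 12 adjusted over the list alone. RPS4X rose by 0.41 and RPL4 by 0.29. Mesenchymal identity genes were lower (median -0.10, adjusted p = 0.00137), with 1 rise, 6 falls and 24 not passed of 31, and 2 and 11 adjusted over the list alone, among them SIX4 (-0.75) and NOTCH2 (-0.48). Interferon response genes were lower (median -0.12, adjusted p = 0.00137), with 1 of 26 falling and 2 adjusted over the list alone, ISG20 at -0.50. TGF-beta and extracellular matrix genes were lower (median -0.20, adjusted p = 0.00867), with 2 rises, 3 falls and 25 not passed of 30 (adjusted over the list alone, 3 and 6), among them COL12A1 (-0.87) and SMAD7 (0.52), but not without KELLY control replicate 1. Mitochondrial transcripts were lower (median -0.23, adjusted p = 0.00867), with 1 of 13 falling in both counts (over all genes and adjusted over the list alone), and this call was lost with quantile normalization and without SKNAS control replicate 2 or KELLY control replicate 1 or 3. The skeletal muscle call (median -0.35, adjusted p = 0.0482), with 1 of 7 falling in both counts, was lost in 12 of 24 alternatives. Its values, like those of the matrix and mesenchymal lists, can include mouse reads. All 6 lists had an adjusted p of 0.84 with an estimated correlation.

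Whether the effect of Hmx1 differed between lines was tested as the difference of the effects. Between SKNAS and LAN-1 it differed for 931 genes, between SKNAS and KELLY for 904, and between LAN-1 and KELLY for 39. Against LAN-1, the SKNAS effect was higher by 5.42 (SE 0.30, adjusted p = 4.79e-09) for CCL2, which stood near 0.05 TPM in both LAN-1 arms (0.0466 and 0.0541), and by 5.56 for MAGEA12 and 5.11 for CSAG1. Against KELLY it was higher by 5.80 for CCL2, 5.58 for MAGEA12 and 5.19 for NPTX2. MAGEA12 stood at 77.1 ± 26.5 and 47.7 ± 28.2 TPM in the KELLY arms. FDCSP and ODAM were listed at 0 in all LAN-1 and KELLY libraries, and CD69 in all KELLY libraries, so that their differences (-4.77, -4.35 and -3.50) repeat the SKNAS changes. GNGT1 differed by -3.68 against LAN-1, where it stood at 0.970 and 1.58 TPM. The share of higher effects against LAN-1 was 59.7%, and 49.1% with quantile normalization. Without KELLY control replicate 2, the effects of SKNAS and KELLY differed for 1357 genes and those of LAN-1 and KELLY for 81; the latter count ranged from 17 to 81 over the libraries left out.

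Between LAN-1 and KELLY, the effect was higher in LAN-1 for CPNE4 (2.67, adjusted p = 0.000871), ENSG00000241962 (2.68, adjusted p = 0.00201) and DAG1 (3.19, SE 0.61, adjusted p = 0.0445). It was lower for ACTL8 (-3.39, adjusted p = 2.59e-06), CD163L1 (-2.73, adjusted p = 0.00577) and CRH (-2.87, SE 0.48, adjusted p = 0.0162). CRH, corticotropin-releasing hormone (ENSG00000147571, chromosome 8, 67088620 to 67090960), stood at 89.2 ± 10.4 and 37.7 ± 12 TPM in the LAN-1 arms and at 29.8 ± 13.1 and 94.2 ± 49.3 in the KELLY arms. CRH lost its call in 4 of 24 alternatives and DAG1 in 14, and CPNE4 (adjusted p = 0.0526) and CD163L1 (adjusted p = 0.0827) lost theirs when the compared groups alone were fitted. As lists, cholesterol synthesis differed between SKNAS and LAN-1 (median -0.78, adjusted p = 8.17e-07; adjusted p = 0.952 with an estimated correlation), with 2 of 23 members, MSMO1 (-1.50) and IDI1 (-1.27), lower over all genes and 9 adjusted over the list alone. Hypoxia genes differed between LAN-1 and KELLY (median -0.48, adjusted p = 1.43e-06; adjusted p = 0.739 with an estimated correlation), with 0 of 30 members lower over all genes and 5 adjusted over the list alone. Unfolded protein response genes differed between SKNAS and KELLY (median -0.52, adjusted p = 0.000549; adjusted p = 0.901 with an estimated correlation), with 2 of 19 members, MANF (-1.39) and SDF2L1 (-1.11), lower and 6 adjusted over the list alone.

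Genes that rose in both SKNAS and LAN-1 numbered 6, where 1.59 would be shared by independent lists (one-sided Fisher's exact test, adjusted p = 0.0131 over 6 tests). They were PDLIM1, TMOD1, DNER, FRRS1L, HAGLROS and ENSG00000273301. Genes that fell in both numbered 9, against 1.98 (adjusted p = 0.000804), and included YBX3, SNCG, CD163L1, MDFI and ST18. The calls of all lines use the same spread estimate per gene, which can raise the overlap of unrelated effects. Fisher's test also counts genes as independent, so these p-values may be too small. At an adjusted p under 0.01 for the genes, 3 rises (adjusted p = 0.0645) and 4 falls (adjusted p = 0.00672) were shared. With median-ratio scaling more genes were shared over all pairs of lines, with the count given below. Genes that rose in SKNAS and fell in LAN-1 numbered 4, against 2.58 for independent lists (adjusted p = 0.771), and 4 went the other way, against 1.22 (adjusted p = 0.192). SKNAS and KELLY shared 1 rise, PP7080, and 0 falls, and LAN-1 and KELLY shared 0 of either; these tests did not pass (adjusted p of 0.734 for the shared rise and 1 for the others). Genes in these counts that lie outside the naming rule were chosen after their values were seen. Of the 1634 genes called in SKNAS, 193 were listed at 0 in all LAN-1 libraries and 191 in all KELLY libraries, and have no sign there. Of the other 1441, 51.4% had the same sign in LAN-1 (95% interval 48.8% to 54.0%, counting genes as if independent, which they are not), where independent signs give 48.3%. Of the other 1443, 51.1% (48.5% to 53.7%) had the same sign in KELLY, where independent signs give 50.7%.

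The control tumours of the 3 lines differed widely. SKNAS control libraries held 1440 TPM of CRABP1, a cytosolic retinoic acid-binding protein, against 0.177 in LAN-1 (log2 difference 10.29, SE 0.32, adjusted p = 4.02e-14). The imprinted gene MEST (578 against 0.638 TPM) and TM4SF4 (291 against 0.0179) were also higher in SKNAS than in LAN-1. MYCN (log2 difference -9.70), NNAT, neuronatin (0.530 against 150.0 TPM), and FGF13, listed at 0 in SKNAS and at 95.7 TPM in LAN-1, were lower. Against KELLY, SKNAS was higher for NEUROG2, a proneural transcription factor (168 against 0.0195 TPM), and for TM4SF4 and the interferon-inducible IFI16 (202 TPM), both listed at 0 in KELLY. It was lower for MYCN (-10.35) and for the neuropeptide genes CARTPT (852 ± 231 TPM in KELLY) and SST, somatostatin (491), both listed at 0 in SKNAS. LAN-1 was higher than KELLY for TMPRSS15, enteropeptidase (659 ± 17.9 against 0.0552 TPM), NNAT (150.0 against 0.363) and UBB (889 against 15.2), and lower for CARTPT (0.0189 against 852), CRABP1 (0.177 against 528 ± 323) and SST, listed at 0 in LAN-1.

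In SKNAS against LAN-1 controls, 5870 genes were higher and 3826 lower (60.5% higher; 51.7% with median-ratio scaling and 49.6% with quantile normalization). In SKNAS against KELLY, 9234 were higher and 3011 lower (75.4% higher; 55.4% with median-ratio scaling, 51.6% with quantile normalization and 64.4% with TPM rescaled without mitochondrial and abundant genes). In LAN-1 against KELLY, 7133 were higher and 2530 lower (73.8% higher; 56.5%, 53.8% and 54.1% in the same order). The median log2 difference of all genes was 0.18, 0.54 and 0.34, and 0.04, 0.11 and 0.06 with median-ratio scaling, so the median of each list is also given relative to the median of all genes. Counts of members and values of single genes are differences from 0.

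Interferon response genes were higher in SKNAS controls, 23 of 26 against LAN-1 with 2 lower (median 2.30, 2.12 relative to all genes, adjusted p = 1.91e-10; 24 and 2 adjusted over the list alone; adjusted p = 0.0579 with an estimated correlation), with IFITM3 at 7.06 and IFI44 at 7.03. Against KELLY, all 26 were higher in both counts (over all genes and adjusted over the list alone; median 2.46, 1.92 relative to all genes, adjusted p = 5.48e-09; adjusted p = 0.109 with an estimated correlation). Mesenchymal identity genes were higher in SKNAS than in LAN-1, 23 of 31 with 2 lower in both counts (median 1.63, 1.45 relative to all genes, adjusted p = 2.68e-06; adjusted p = 0.32 with an estimated correlation), with LGALS1 at 4.40, NOTCH2 at 3.88 and SNAI2 at 3.39. Noradrenergic identity genes were lower in SKNAS than in LAN-1, 15 of 25 with 4 higher (5 adjusted over the list alone; median -0.85, -1.03 relative to all genes, adjusted p = 0.000125; adjusted p = 0.431 with an estimated correlation), with GATA2 at -4.84, TH at -4.35 and TFAP2B at 3.82. Bridge and committed progenitor genes were higher in LAN-1 than in KELLY, 9 of 11 with 1 lower in both counts (median 2.22, 1.88 relative to all genes, adjusted p = 0.00305; adjusted p = 0.116 with an estimated correlation), with NEUROG2 at 4.84 and DLL1 at 2.91. Mitochondrial transcripts were lower in LAN-1 than in KELLY, all 13 in both counts (median -1.90, -2.24 relative to all genes, adjusted p = 2.38e-09; adjusted p = 0.323 with an estimated correlation).

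Along the chromosomes, genes within some stretches of 10 Mb moved together between arms. This was looked for after 5 of the 10 named LAN-1 rises (FRRS1L, TMOD1, AOPEP, PRSS3 and ASS1) were seen on chromosome 9, and its thresholds were set after seeing the data. A stretch was counted as shifted where it held at least 15 genes with a mean of at least 5 TPM, its median log2 change was at least 0.25 away from that of all such genes, and the arms did not overlap. Of 264 stretches, 11 were shifted up and 1 down in SKNAS, 8 up and 3 down in LAN-1, and 0 in KELLY. In SKNAS, chromosome 1 from 0 to 20 Mb had a median of 0.57 with 141 of 157 genes on the same side, and chromosome 13 from 90 to 120 Mb a median of 0.47 with 52 of 57. In LAN-1, chromosome 9 from 80 to 140 Mb had a median of 0.31 (269 of 310 genes), chromosome 18 from 0 to 20 Mb a median of 0.44 (48 of 53), and chromosome 8 from 140 to 150 Mb a median of -0.37 (67 of 68). FRRS1L, TMOD1, AOPEP and ASS1 lie in the shifted part of chromosome 9, ENPP2 in a LAN-1 stretch of chromosome 8 that was shifted down, BIVM-ERCC5 in the SKNAS stretch of chromosome 13, and CSTF2T in a SKNAS stretch of chromosome 10 that was shifted down. IRS2 lies in the SKNAS stretch of chromosome 13 as well, but it fell whereas that stretch was shifted up. Members of the gene lists named above were not placed in this way, so the change of a single member can be part of the shift of its stretch.

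**Figure D3:**
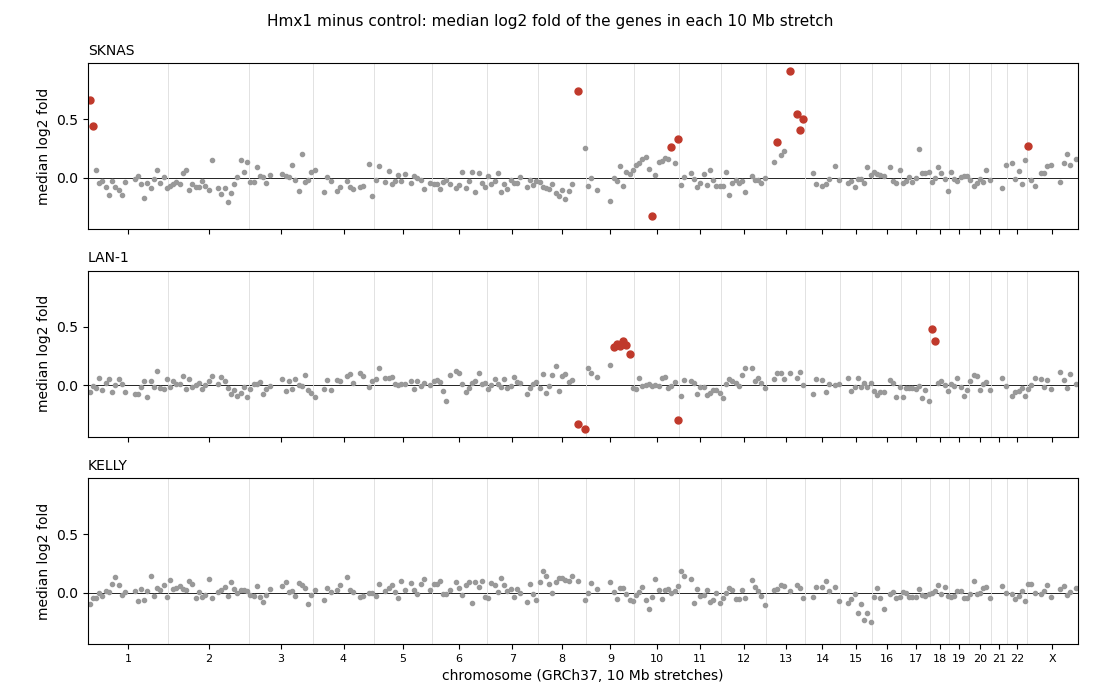
Median log2 change (Hmx1 minus control) of the genes in each 10 Mb stretch along the chromosomes (GRCh37), by line; each point is a stretch, and red points are those counted as shifted. SKNAS has 12 such stretches, LAN-1 has 11 and KELLY has 0.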

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

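The differences of effects and the relabellings of libraries were planned, whereas the tests of KELLY spread and of chromosome stretches below were chosen after the counts of changed genes were seen. What marked these results is a test of the difference between the Hmx1 effects of 2 lines in limma. No group held enough libraries for a test of outlying samples.

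Between SKNAS and LAN-1 the Hmx1 effect differed for 931 genes, between SKNAS and KELLY for 904 and between LAN-1 and KELLY for 39. SKNAS against LAN-1, the effects of MAGEA12 (5.56), CCL2 (5.42) and CSAG1 (5.11) were higher on the log2 scale, and those of FDCSP (-4.77), ODAM (-4.35) and GNGT1 (-3.68) lower. SKNAS against KELLY, CCL2 (5.80), MAGEA12 (5.58) and NPTX2 (5.19) were higher, and FDCSP (-4.77), ODAM (-4.35) and CD69 (-3.50) lower. LAN-1 against KELLY, DAG1 (3.19), ENSG00000241962 (2.68) and CPNE4 (2.67) were higher, and ACTL8 (-3.39), CRH (-2.87) and CD163L1 (-2.73) lower. MAGEA12 and CSAG1 have near-identical relatives, and DAG1 lost its call in 14 of 24 alternatives.

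More genes changed in SKNAS (1634) than in KELLY (17). Larger spread between KELLY libraries would leave KELLY folds as wide as those of SKNAS. The measured KELLY folds were narrower: their variance over 11890 genes, spread included, was 0.0849 (95% interval 0.0797 to 0.0906). That of SKNAS, after its spread was taken off, was 0.159 (0.142 to 0.177). These intervals resample genes and carry no uncertainty from the libraries. The KELLY spread alone predicted 0.123, more than the 0.0849 seen, so the spread estimate does not describe the KELLY folds. The comparison of variances therefore decides nothing on spread. The fit, however, used the same spread estimate per gene in all lines, so each line was tested with the same SE (for HMX1, 0.238 in SKNAS, LAN-1 and KELLY). Larger spread in KELLY thus did not make its test stricter than that of SKNAS, which argues against spread as the source of the lower KELLY count. Leaving out mitochondrial genes and the 50 most abundant genes gave 1899 SKNAS genes, and 1489 of the 1634 lay outside shifted stretches, so neither accounts for the difference. A larger response of SKNAS is a hypothesis that no test here decides. The calls outside shifted stretches do not exclude SKNAS arms grown from different subclones, a candidate given below for the stretches. It stays open whether the arms of the lines differed in how much Hmx1 they carried, since HMX1 itself passed the test over all genes in none of the lines.

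Splitting the 6 libraries of a line into 3 and 3 in another way gives 10 splits, too few for a share under 0.05. In SKNAS, 1 of 10 splits, the real one, gave 1634 genes, and the highest other gave 5. In LAN-1, 1 of 10 gave 84 and the highest other 7. In KELLY, 4 of 10 splits gave at least the 17 genes of the real one, and the highest gave 156, which points to a structure of the samples. On the first principal component of KELLY (46.4% of the variance), control replicates 1 and 2 lay furthest apart, at 57.4 and -49.4; what this structure is was not tested. For the controls, 1 of 10 splits, the real one, gave as many genes in each comparison: 9696 against a highest other of 1 for SKNAS and LAN-1, 12245 against 3 for SKNAS and KELLY, and 9663 against 0 for LAN-1 and KELLY. Every split was fitted anew, and a split that mixes lines or arms puts their difference into the spread estimate. Low counts in the other splits of the controls, SKNAS and LAN-1 follow in part from this, so the gap to the real count is no added evidence.

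Relabelling the arms within each line gave 100 labellings, the real one included. As many genes as in the mean effect (660) came from 2 of 100 labellings, the real one among them, with a highest other of 984. That share is under 0.05 for chance labels in all lines at once. A relabelling can by design keep the real SKNAS arms, and 581 of the 660 genes were also called in SKNAS. The share therefore does not exclude that SKNAS alone gave the count. For SKNAS against LAN-1 (931), 1 of 100 gave as many, with a highest other of 898. For SKNAS against KELLY (904), 4 of 100 did, with a highest other of 1353. Between LAN-1 and KELLY (39), 4 of 100 did, with a highest other of 656, several times the real count, which again points to a structure of the samples. What it is and in which line it lies was not tested.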

How the results depend on the processing

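Means over pairs of lines, the mitochondrial covariate and genes outside shifted stretches were alternatives chosen after seeing the data, and the others were planned. Of 2199 alternative values of 104 named gene changes, 2081 kept direction and call, 0 reversed and the others lost the call. These changes were picked as the largest that passed in the same libraries, so that choice in part sets the kept share. Of 573 alternative list tests, 502 kept the call, 69 lost it and 2 reversed: KELLY mitochondrial transcripts without KELLY control replicate 1 (adjusted p = 0.976; 5.85e-23 without KELLY control replicate 2) and KELLY ribosomal proteins without KELLY Hmx1 replicate 3 (adjusted p = 0.915; 4.17e-10 without KELLY control replicate 1). With correlations estimated, 0 of the 23 list calls remained. No paired analysis was possible because the labels give the libraries no shared replicate numbers. TPM keeps no depth, so what depth limits cannot be stated.

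HMX1 in SKNAS passed with a pseudocount of 0.1 (2.55) and with library weights (0.65). Without a filter, LAN-1 had 127 changed genes and KELLY 49. A minimum of 5 TPM, which tests fewer genes, gave 1028 in SKNAS, 45 in LAN-1, 10 in KELLY, 419 in the mean, and 574, 567 and 17 for the differences SKNAS minus LAN-1, SKNAS minus KELLY and LAN-1 minus KELLY. FPKM gave 137 in LAN-1. Median-ratio scaling gave 160 in LAN-1, 62 for LAN-1 minus KELLY and an overlap of 31 genes between lines (16 as reported). Quantile normalization gave 162 in LAN-1, 1399 for SKNAS minus KELLY and 63 for LAN-1 minus KELLY. Fitting the compared groups alone gave 27 in LAN-1, 0 in KELLY, 1522 for SKNAS minus LAN-1 and 8 for LAN-1 minus KELLY. Library weights gave 2899, 2254 and 3802 genes in SKNAS, LAN-1 and KELLY, 3221 in the mean, and 3079, 3746 and 3264 for the differences. Their estimate did not converge and gave KELLY control replicates 1 and 3 weights of 0.0768 and 130.0, whereas SKNAS weights ran from 0.70 to 1.19 and LAN-1 weights from 0.333 to 2.50. The cause of the higher counts was not tested.

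A log2 change of at least 1 was reached by 788 changed genes in SKNAS, 49 in the mean and, between controls, 5362 (SKNAS and LAN-1), 7479 (SKNAS and KELLY) and 5026 (LAN-1 and KELLY), counts that are lower by construction. The overlap was 10 genes with that threshold and 7 at an adjusted p under 0.01. The mean over LAN-1 and KELLY alone had 28. With the mitochondrial share as a covariate, SKNAS had 1766 changed genes, LAN-1 80 and KELLY 18. The cause of the other moves was not tested.

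Leaving out each library gave 1211 to 1397 changed genes in SKNAS, 53 to 99 in LAN-1, 15 to 49 in KELLY, 490 to 844 in the mean, 706 to 930 for SKNAS minus LAN-1, 689 to 1357 for SKNAS minus KELLY and 17 to 81 for LAN-1 minus KELLY. Between controls it gave 8539 to 8862, 11182 to 12827 and 8382 to 10691. List calls numbered 20 to 27. The HMX1 change ranged from 0.38 to 0.83 in SKNAS, from -0.01 to 0.24 in LAN-1 and from -0.22 to 0.20 in KELLY. LAN-1 counts moved by over 1.5 times without control replicate 1 (54), control replicate 2 (54), Hmx1 replicate 2 (53) or Hmx1 replicate 3 (54), KELLY counts without control replicate 1 (29), control replicate 2 (49) or Hmx1 replicate 1 (27), and SKNAS minus KELLY without KELLY control replicate 2 (1357). LAN-1 minus KELLY moved without LAN-1 control replicate 1 (20), 2 (25) or 3 (24), LAN-1 Hmx1 replicate 2 (17), KELLY control replicate 1 (62) or 2 (81), or KELLY Hmx1 replicate 2 (25).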

Other observations

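The analysis of chromosome stretches, their thresholds and all tests in the next paragraphs were chosen after the results were seen, and NDUFA5P9, HTR1E and NDUFA5 were chosen after their values were seen.

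Of the SKNAS rises, 52 of 925 (5.60%) were X-linked, against 3.60% of the genes tested (Fisher's exact test, adjusted p = 0.00816 over 6 tests). This count was made after X-linked cancer-testis genes, among them MAGEA12, MAGEA2B, MAGEA3, MAGEA6, CSAG1 and CTAG1B, were seen among the largest rises, and it treats neighbouring, near-identical copies as independent genes. With the 26 tested members of such families left out, 11 of which were SKNAS rises and 2 SKNAS falls, 41 of 914 rises were X-linked (4.50%, against 3.40%) and the difference did not pass (adjusted p = 0.23 over 6 tests). An X-linked excess beyond these families was thus not shown. The SKNAS falls (17 of 709, adjusted p = 0.195) and the LAN-1 and KELLY calls did not pass with the families included.

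Whole stretches of chromosomes moved together in SKNAS (12 stretches; at most 1 in another split of the libraries) and in LAN-1 (11; at most 0), and 10 splits are too few for a share under 0.05. A GC trend does not account for them, since 12 of 12 and 11 of 11 stayed past 0.25 after it was removed, nor do a few strongly changed genes for the stretches as a set: in 19 SKNAS and 11 LAN-1 stretches picked on every other gene, 77.6% of 312 and 90.5% of 400 uncalled genes held out lay on the side of the stretch. For 5 of the 12 SKNAS stretches a few genes stay open, since their median over uncalled genes was under 0.25, as for chromosome 13 from 70 to 80 Mb (0.184, against 0.913 over all its genes). Unequal gene copy number in the cells of the arms, such as arms grown from different subclones, is a candidate explanation: genes of low and of high expression moved the same way in 12 of 12 and 11 of 11 stretches, a test that the choice of stretches makes nearly void. Copy number and an effect of Hmx1 cannot be told apart, because no DNA was measured and each arm may hold its own cell population.

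NDUFA5P9, a processed pseudogene (GRCh37 chromosome 6, 86923955 to 86924297), stood at 354 to 689 TPM (472 ± 188, n = 3) in LAN-1 Hmx1 libraries and at no more than 0.169 in the 15 others (log2 change 8.74, SE 0.20, adjusted p = 1.13e-14). Reads shared with its parent gene NDUFA5 would show wherever NDUFA5 is present, yet the other libraries held at least 102 TPM of NDUFA5, which stood at 147 ± 16.4 and 141 ± 18.5 in the LAN-1 arms, and no more than 0.169 of NDUFA5P9. Activation of the surrounding region stays open, since 0 of 8 tested genes within 1 Mb rose and 8 genes are few. Among these, HTR1E fell from 4.46 to 0.839 TPM (-1.57, adjusted p = 0.00108). No test here tells a sequence introduced into or near the locus from a change of its own expression, and no biological explanation was tested.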
